A study of Homo sapiens with 6 samples.

How the data were processed

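Messenger RNA was measured by sequencing in 6 cultures of human airway epithelium, 3 normal and 3 squamous. Per the labels, airway basal cells were expanded, seeded on permeable membranes and differentiated at an air-liquid interface (ALI) for 14 to 21 days, with the medium below and air above. Per the labels' protocols, the squamous group received 2 uM CHIR99021 during ALI differentiation and the normal group did not. CHIR99021 inhibits glycogen synthase kinase 3, which activates canonical Wnt signalling, and per the labels it was also present in the medium in which the basal cells of both groups were expanded. Libraries were prepared with a SMARTER mRNA-seq kit, per the labels' protocols. The labels do not say whether the replicates came from separate donors, cultures or days, so p-values measure the spread between these samples, which may be technical. The labels give no batch.

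The authors deposited a single table with 1 line per gene. Its read counts per gene and library are whole numbers, taken as the authors' raw counts because they are unscaled and sum to a different total in each library. A parallel signal column per library holds the authors' normalized counts, each a constant multiple of the raw column, and baseMean is the mean of these 6 signal columns, per the file headers. Per the file headers, the log2 fold change of squamous over normal, its standard error, a test score (the fold change divided by its error), p-values and adjusted p-values are those of a DESeq2-type comparison by the authors. The exon lists and gene lengths have the layout that featureCounts writes. The aligner, counting tool, strand setting and genome build are not given in the sources used here. The contig names are those of the UCSC hg19 assembly, and coordinates are printed as the table gives them. All 16837 genes listed have at least 10 counts over the 6 libraries. Date-like names replaced 21 gene symbols, which hold 0.2% of counts; those genes were tested but never named. The columns named ALI were taken as the normal group because the other set carries the name of the squamous group, and replicate numbers follow the labels. No column of values was left without a sample. A refit with DESeq2 1.42.0 gave fold changes within 0.01 of the deposited ones for 100% of genes.

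Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (14637 of 16837), libraries were scaled by TMM, and the robust quasi-likelihood F test compared squamous with normal with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Levels are CPM, each library's counts scaled to a common total after TMM, as mean ± SD over 3 libraries. The SE of a log2 fold change is the unshrunk coefficient divided by the square root of the F statistic. Library totals ranged from 17107111 to 21692713 counts. A single count was worth 0.0449 to 0.061 CPM, and 3 counts, used as the floor of detection, were worth 0.135 to 0.183 CPM; the floor covers counting error only. Replicates of a group correlated at 0.991 to 0.992 (Pearson, log2 CPM with a prior count of 2, across genes). Their counts differed by more than sampling noise in every pair (chi-square per gene of 5.38 to 9.14), so each library counted as 1 replicate.

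Before the data were examined, 29 gene lists were fixed from textbook knowledge of airway and stratified epithelium. They cover squamous keratins, the cornified envelope, desmosomes, epithelial cell types, signalling pathways, host defence, metabolism, other cell types the cultures could hold, and stress genes. Symbols absent from the table were looked up among older symbols, which found 8 members. Lists of at least 3 tested genes were compared with all other genes by camera (limma 3.58.1, two-sided) with a preset inter-gene correlation of 0.01, adjusted over the 29 lists. Camera with an estimated correlation and fry were run beside it. Members were counted past the threshold over all genes, and also when adjusted over the list alone. Markers were also compared by an exact permutation test, which cannot go below 0.1 with 3 against 3.

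The genes named in the text follow a rule fixed beforehand. It takes 8 markers (KRT13, KRT5, TP63, FOXJ1, SCGB1A1, MUC5AC, AXIN2, LEF1) and the 10 largest rises and 10 largest falls past the threshold. Those 20 needed at least 10 CPM in the higher group and no overlap between groups, and sex-linked, immune receptor and mitochondrial genes were left out. From each list it takes up to 2 largest rises and 2 largest falls past the threshold, or the 2 members of highest mean if none passed. MUC5AC is not analysed here, and not every gene the rule takes is printed. Other members named as examples were chosen after their values were seen. Reads can be shared between near-identical copies, so values of KRT6A, KRT6B, KRT6C, the SPRR2 family, KRT42P, GSTA2, CEACAM5, CEACAM6 and HLA genes are uncertain, as are those of antisense or overlapping genes and of the genes on more than 1 contig (169, such as HLA-DPB1, TAP1, IER3 and HSPA1A).

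On data simulated for this comparison (14637 genes, 14512 tested), the edgeR step recovered 42% of genes changed 1.25-fold, 74% changed 1.5-fold, 96% changed 2-fold and 100% changed 4-fold. Each fold was given to 50 genes, so a far smaller share changed than the 51% called in the data. The adjusted threshold depends on that share, so these percentages may not hold for the data. Over 5 draws, 6.99% of the edgeR calls were false, against 7.71% for DESeq2, both above the nominal 5%. A planted list was found by camera with either correlation, and 0 of 20 random lists were called. The simulated genes were drawn independently, so this could not test the preset correlation for lists whose members move together. The alternatives were RLE and upper-quartile scaling, DESeq2 and limma-voom, no filter and a filter of 1 CPM in 3 libraries, a minimum fold of 2 (glmTreat), the replicate number as a block, and leaving out each library in turn. Plots were drawn with matplotlib 3.10.9.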

Results

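RNA was sequenced from 6 air-liquid interface cultures of human airway epithelium, 3 of normal airway epithelium and 3 of squamous epithelium made by adding 2 uM CHIR99021 during differentiation. The comparison asks which genes differ between the normal mucociliary culture and the squamous culture. Normal replicates 1 to 3 held 21692713, 17107111 and 17649789 counts, and squamous replicates 1 to 3 held 17150713, 17508000 and 20109349. The 10 most abundant genes held 4.23% to 5.98% of the counts. The first principal component held 77.7% of the variance of log2 CPM.

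In squamous cultures, 10 of 11 squamous keratins, 17 of 29 cornified envelope genes and 19 of 25 inflammatory cytokine genes rose, and 39 of 41 multiciliated cell genes fell. Camera called these 4 lists with a preset correlation (adjusted p = 0.59 for each with an estimated correlation). The keratin and envelope counts were smaller in several other fits, given below. KRT13, the keratin whose staining the study used to check squamous differentiation, rose from 247 ± 45.3 to 1870 ± 201 CPM (SD, n = 3 in each group), a log2 fold change of 2.93 (SE 0.16, edgeR adjusted p = 5.61e-06). The basal keratin KRT5 rose from 1530 ± 141 to 3480 ± 70.8 CPM (log2 fold change 1.19), whereas the basal transcription factor TP63 measured 157 ± 10.8 and 158 ± 12.4 CPM (edgeR adjusted p = 0.903). FOXJ1, a master regulator of motile cilia, fell from 1390 ± 58.3 to 1000 ± 111 CPM (log2 fold change -0.47). Among 14637 genes tested, 7464 (51%) differed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 3585 higher and 3879 lower in squamous cultures. Of these, 508 were at least 2-fold higher and 1166 at least 2-fold lower. The median size of a called change was 0.512 on the log2 scale, and a test against a minimum fold of 2 called 649 genes, 186 higher and 463 lower. The groups did not overlap at 8656 genes (59.1%), where chance gives 10%. In the two-sided exact permutation test, 3 libraries against 3 cannot give a p below 0.1, the value for KRT13, KRT5 and FOXJ1. The authors' deposited table has 7092 genes at an adjusted p under 0.05, 3528 higher and 3564 lower, and 6888 of them were also called by edgeR.

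**Figure D1:**
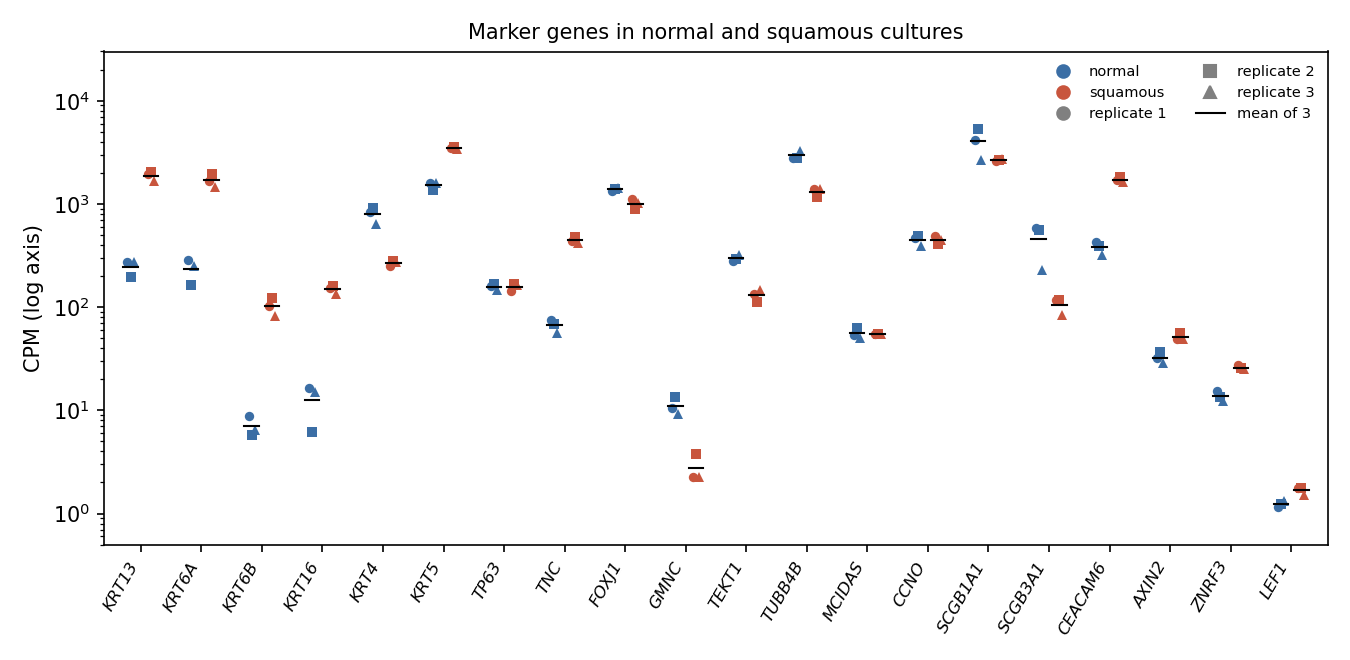
CPM on a log axis of 20 marker genes in each of the 6 libraries, blue for normal and red for squamous, with symbols for replicates and a bar for the mean of 3. KRT13 lay at 194 to 274 CPM in the normal and 1650 to 2030 CPM in the squamous libraries, while MCIDAS and CCNO overlapped between groups.

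Keratins of stratified epithelium had the largest median rise among the 29 lists. Of 11 tested squamous keratins, 10 rose and KRT4 fell, with a median log2 fold change of 2.86 (camera adjusted p = 0.000791; adjusted p = 0.59 with an estimated correlation). The number higher was 8 with the replicate number as a block and without any 1 normal replicate or squamous replicate 2. Without squamous replicate 1 it was 7. KRT6C and KRT6B, keratins of wounded and hyperproliferative epithelium, rose by 4.78 (SE 0.21) and 3.84 (SE 0.21) on the log2 scale, and KRT16 rose from 12.6 ± 5.61 to 149 ± 13.6 CPM, log2 fold change 3.55. KRT6A reached 1690 ± 242 CPM, but reads can be shared among the KRT6 copies, so the split among them is uncertain. KRT13 (chromosome 17, 39657233 to 39661865) is usually paired with KRT4 in non-cornifying mucosa. KRT4 (chromosome 12, 53200327 to 53207900) fell from 803 ± 144 to 268 ± 16.6 CPM, log2 fold change -1.59 (edgeR adjusted p = 6.59e-06).

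More cornified envelope genes rose than fell, with wide spread among the squamous libraries. Of 29 tested, 17 rose and 0 fell in edgeR, where 0 fell also at an unadjusted p under 0.05, and DESeq2 called 24 of 36 higher and 0 lower. The median log2 fold change was 1.22 (camera adjusted p = 5.39e-06; adjusted p = 0.59 with an estimated correlation). The small proline-rich genes SPRR2E and SPRR2F, precursors of the envelope, rose by 3.74 (SE 0.88, edgeR adjusted p = 0.0254) and 3.58 (SE 1.00, edgeR adjusted p = 0.0414) on the log2 scale. Both calls were lost without any 1 of the normal replicates or squamous replicate 1 (edgeR adjusted p of 0.0616 to 0.092 for SPRR2E and 0.0825 to 0.131 for SPRR2F) and in limma-voom (adjusted p = 0.123 and 0.177). Squamous replicates 1, 2 and 3 measured 36.6, 75.6 and 13.4 CPM of SPRR2E, and 25 of the 29 members were higher in replicate 2 than in replicate 3. Without squamous replicate 3, 25 of 32 members were higher, and without squamous replicate 2, 17 of 31 were higher and 2 lower. The number higher was 11 without normal replicate 2, normal replicate 3 or squamous replicate 1, and 9 of 29 with the replicate number as a block.

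Genes of desmosomes and basal cells also changed. Of 10 desmosome genes, 8 rose and PERP fell (camera adjusted p = 0.00413; adjusted p = 0.59 with an estimated correlation), led by the cadherins DSC2, from 9.67 ± 1.11 to 43.7 ± 2.82 CPM, and DSG3, from 30.3 ± 6.8 to 74.7 ± 9.25 CPM. PERP fell by only 0.19 on the log2 scale. Of 23 basal cell genes, 12 rose and 3 fell, or 13 and 3 when adjusted over the list alone (camera adjusted p = 0.00652; adjusted p = 0.59 with an estimated correlation). Tenascin C (TNC), a matrix glycoprotein, rose from 66.5 ± 9.53 to 445 ± 28.8 CPM, and KRT17 from 271 ± 104 to 707 ± 116 CPM (edgeR adjusted p = 0.0382). The KRT17 call was lost without any 1 library other than normal replicate 2 (edgeR adjusted p of 0.0639 to 0.109). BCAM and DLK2 fell by 0.83 and 0.72 on the log2 scale.

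Nearly all multiciliated cell genes fell, though not equally. Of 41 tested, 39 fell and 0 rose in edgeR, with 0 higher also at an unadjusted p under 0.05 and 0 in DESeq2. The median log2 fold change was -1.21 (camera adjusted p = 1.14e-14; adjusted p = 0.59 with an estimated correlation). DYNLRB2, a dynein light chain, fell from 48.2 ± 3.09 to 13.1 ± 1.01 CPM, log2 fold change -1.87 (SE 0.09). GMNC, which initiates the multiciliated programme, fell from 11.1 ± 2.11 to 2.76 ± 0.853 CPM, log2 fold change -2.01 (SE 0.20). The members not past the threshold were MCIDAS, at 55.7 ± 6.56 and 55 ± 0.338 CPM, and CCNO, at 451 ± 52.4 and 449 ± 42.4 CPM; both act early in making the many centrioles of these cells. The smallest falls past the threshold were those of CDC20B and CCDC67 (DEUP1), by 0.22 and 0.38 on the log2 scale (edgeR adjusted p = 0.0135 and 0.00748). TCTEX1D4, a dynein light chain gene outside the list, was among the 10 largest falls, from 56 ± 10.9 to 9.58 ± 0.974 CPM.

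**Figure D2:**
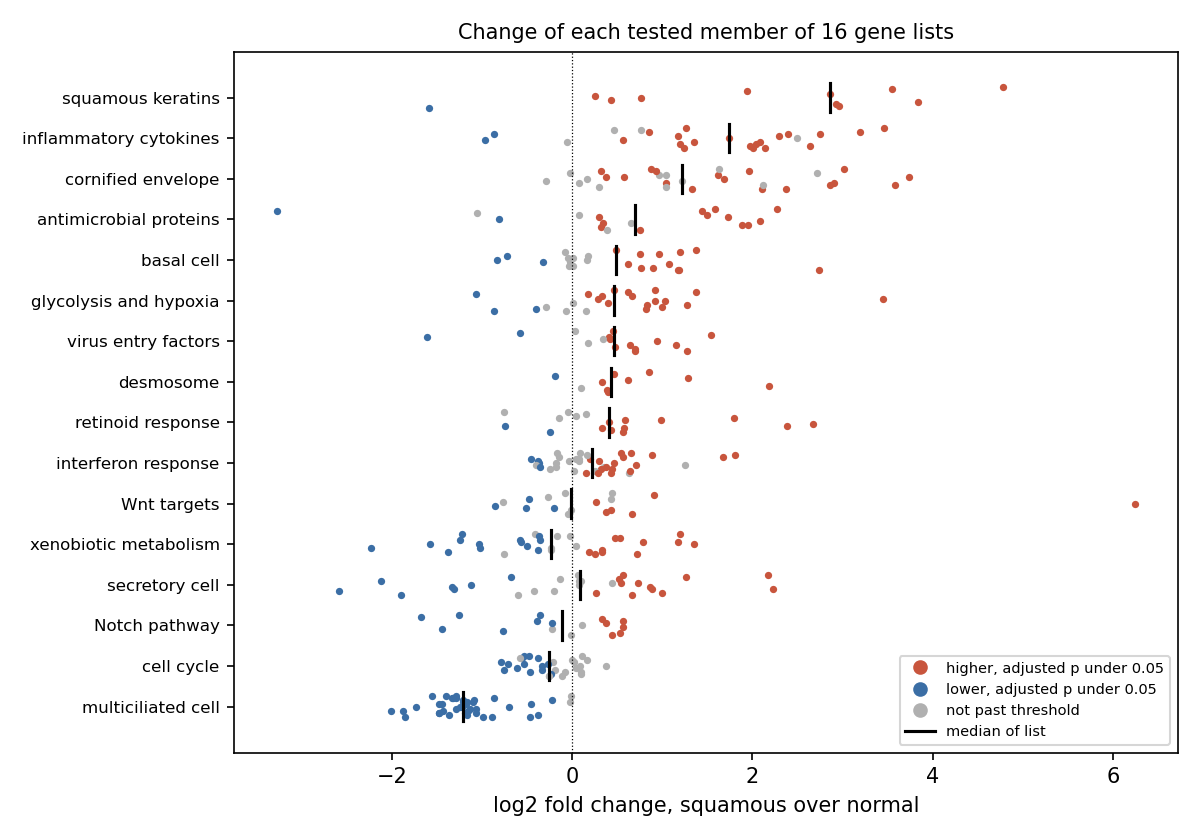
Log2 fold change of each tested member of 16 gene lists, coloured by whether it passed an edgeR adjusted p under 0.05, with a bar at each list's median. The medians ran from -1.21 for multiciliated cell genes to 2.86 for squamous keratins.

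Secretory, ionocyte and neuroendocrine markers went both ways. Of 28 secretory genes, 12 rose and 7 fell, or 12 and 8 when adjusted over the list alone (camera adjusted p = 0.335). The club cell gene SCGB1A1 measured 4040 ± 1310 and 2660 ± 40.2 CPM (edgeR adjusted p = 0.144). It depended on normal replicate 3, without which the log2 fold change was -0.82 (edgeR adjusted p = 6.62e-09). SCGB3A1 fell from 459 ± 200 to 106 ± 18.6 CPM (edgeR adjusted p = 0.0185), a call lost without any 1 library other than normal replicate 3 (edgeR adjusted p of 0.0573 to 0.0713). The intelectin ITLN1 fell from 2.27 ± 0.579 to 0.366 ± 0.17 CPM. The adhesion molecules CEACAM5 and CEACAM6 rose to 781 ± 106 and 1720 ± 98 CPM, by 2.23 and 2.17 on the log2 scale. Of 6 ionocyte genes, 1 rose and 3 fell (camera adjusted p = 0.599), among them the ionocyte factor FOXI1, from 152 to 40 counts over the group. TFCP2L1 rose by 0.27 on the log2 scale (edgeR adjusted p = 0.0423), a call lost in DESeq2 (adjusted p = 0.0571) and without normal replicate 2 or 3 or squamous replicate 2 or 3 (edgeR adjusted p of 0.0809 to 0.132). Of 5 tuft cell genes, 0 were called by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.846); LRMP and PLCG2 were at 65.4 and 5.53 CPM in normal cultures, and PLCG2 was called without normal replicate 3 (log2 fold change 0.64, edgeR adjusted p = 0.0068). Of 6 neuroendocrine genes, 3 rose and 1 fell (camera adjusted p = 0.312), at low counts: INSM1 had 16 counts over the normal and 45 over the squamous libraries, and SCG3 had 194 and 81. That list was called without squamous replicate 3 (camera adjusted p = 0.0332) and with no filter (camera adjusted p = 0.024). Without squamous replicate 3 or any 1 of the normal replicates, 5 of 8 tested were higher and 1 lower, and DESeq2 called 5 of 12 higher and 1 lower.

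Targets of Wnt signalling, the pathway that CHIR99021 activates, changed in both directions. Of 17 tested, 6 rose and 4 fell, with a median log2 fold change of -0.01, a mean of 0.38 and a camera direction of up (adjusted p = 0.523). Fry, which asks whether the list's own genes move one way, did call this list (fry adjusted p = 0.00248). Without squamous replicate 3, 6 were higher and 2 lower. AXIN2, a feedback target of the pathway, rose from 32.5 ± 4.17 to 51.5 ± 4.22 CPM, log2 fold change 0.67 (SE 0.09, edgeR adjusted p = 7.85e-06), and the ubiquitin ligase gene ZNRF3 rose from 13.8 ± 1.53 to 26 ± 1.11 CPM. LGR6, an R-spondin receptor, went from 6 counts over the normal libraries to 440 over the squamous, with a fitted log2 fold change of 6.24 that depends on the prior count. LEF1, a transcription factor of the pathway, had 72 counts over the normal and 89 over the squamous libraries (edgeR adjusted p = 0.23). TNFRSF19 and TCF7 fell by 0.85 and 0.51 on the log2 scale. Of 16 Notch pathway genes, 6 rose and 7 fell, or 6 and 8 when adjusted over the list alone (camera adjusted p = 0.846). The ligand JAG2 and the receptor NOTCH3 each rose by 0.57 on the log2 scale, while the ligand DLL1 fell from 57.8 ± 8.66 to 21.3 ± 1.02 CPM and the target HEYL fell by 1.68. Of 30 cell cycle genes, 14 fell and 0 rose in edgeR (1 higher at an unadjusted p under 0.05, 0 in DESeq2), with TOP2A and CENPF lower by 0.79 and 0.76 (camera adjusted p = 0.0288; adjusted p = 0.59 with an estimated correlation). The other 16 were not called, among them MKI67 (log2 fold change -0.25, edgeR adjusted p = 0.216) and PCNA (0.11, edgeR adjusted p = 0.279). That list's call was lost without normal replicate 1 (camera adjusted p = 0.0628) and without squamous replicate 2 (camera adjusted p = 0.0743), where 1 member was higher.

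Cytokine and antimicrobial transcripts were mostly higher in squamous cultures. Of 25 inflammatory cytokine genes, 19 rose and 2 fell, with a median log2 fold change of 1.74 (camera adjusted p = 1.44e-06; adjusted p = 0.59 with an estimated correlation). The cytokine IL19 rose from 2.78 ± 0.404 to 30.8 ± 3.45 CPM, log2 fold change 3.46 (SE 0.14), and IL36RN, an antagonist of interleukin-36 receptors, by 3.19 (SE 0.51). TSLP and CCL28 fell by 0.96 and 0.86. Of 18 antimicrobial genes, 12 rose and 2 fell (camera adjusted p = 0.00652; adjusted p = 0.59 with an estimated correlation). In squamous replicate 2, 20 of the cytokine and 15 of the antimicrobial genes were higher than in replicate 3. The calprotectin subunit gene S100A8 rose from 68.1 ± 10.2 to 329 ± 92.6 CPM and RNASE7 by 2.09 on the log2 scale. NOS2, the inducible nitric oxide synthase, fell from 19.3 ± 4.48 to 1.99 ± 0.36 CPM, log2 fold change -3.27, and lactoferrin (LTF) from 142 ± 19.1 to 80.9 ± 11.1 CPM. Of 38 interferon response genes, 17 rose and 4 fell, by a median of 0.22 over the list (camera adjusted p = 0.0369; adjusted p = 0.59 with an estimated correlation). That list's call was lost without squamous replicate 1 (camera adjusted p = 0.0996), squamous replicate 2 (0.0694) or normal replicate 2 (0.0577), and with the filter of 1 CPM in 3 libraries (0.0517). IFI44L and OASL rose by 1.81 and 1.67 from low levels, while ISG20 and MX1 fell by 0.46 and 0.38. Of 22 antigen presentation genes, 9 rose and 3 fell (camera adjusted p = 0.139, or 0.0347 without normal replicate 1); TAP1 rose by 0.59, and HLA-DQA1 and HLA-DPB1 each fell by 1.13 on the log2 scale. Of 15 pattern recognition receptor genes, 7 rose and 3 fell, or 8 and 3 when adjusted over the list alone (camera adjusted p = 0.113), with TLR4 and NLRP1 higher by 1.37 and 0.74 and NOD2 and DHX58 lower by 1.42 and 0.63. Of 16 virus entry factor genes, 11 rose and 2 fell (camera adjusted p = 0.00422; adjusted p = 0.59 with an estimated correlation). DPP4 rose by 1.54 on the log2 scale. CDHR3, a rhinovirus C receptor of multiciliated cells, fell from 215 ± 30.2 to 70.3 ± 9.6 CPM, and the protease gene CTSL fell by 0.58.

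Camera called the retinoid response list and the glycolysis and hypoxia list higher in squamous cultures, each with members that fell, and other metabolic and transport lists went both ways. Of 17 retinoid response genes, 10 rose and 2 fell, or 10 and 3 when adjusted over the list alone (camera adjusted p = 0.00652; adjusted p = 0.59 with an estimated correlation). RARRES1, a gene induced by retinoic acid, rose from 27.2 ± 1.39 to 172 ± 14.2 CPM, and the retinol transporter STRA6 from 7.72 ± 1.05 to 40.1 ± 0.941 CPM. The retinal dehydrogenase ALDH1A1 fell from 1420 ± 13.9 to 847 ± 14.1 CPM, and CRABP2 by 0.24 on the log2 scale (edgeR adjusted p = 0.0162), a call lost without normal replicate 1 (edgeR adjusted p = 0.144), squamous replicate 2 (0.0813) or squamous replicate 3 (0.0897). In each of those 3 fits 1 member of the list was lower, and without normal replicate 3 there were 4. Of 23 glycolysis and hypoxia genes, 16 rose and 3 fell, or 17 and 3 when adjusted over the list alone (camera adjusted p = 0.000909; adjusted p = 0.59 with an estimated correlation). The carbonic anhydrase CA9 went from 26 to 261 counts over the group and adrenomedullin (ADM) from 13.7 ± 2.05 to 35.6 ± 1.3 CPM, while ANKRD37 and ENO2 fell by 1.06 and 0.87. Of 31 xenobiotic metabolism genes, 11 rose and 13 fell, or 11 and 14 when adjusted over the list alone (camera adjusted p = 0.42). The glutathione transferase gene GSTA2 fell from 93.2 ± 10.4 to 19.8 ± 1.05 CPM and SULT1E1 by 1.57, while CYP3A5 and CYP2B6 rose by 1.35 and 1.20. Of 19 ion and fluid transport genes, 7 rose and 7 fell, with a median of -0.11, a mean of -0.34 and a camera direction of up (adjusted p = 0.977). The chloride channel gene BEST4 went from 243 to 17 counts over the group and KCNJ16 from 350 to 49, while KCNE3 and SLC26A9 rose by 1.08 and 0.96. Of 21 tight junction and polarity genes, 7 rose and 7 fell, or 7 and 8 when adjusted over the list alone, with a median of 0.02, a mean of -0.07 and a camera direction of up (adjusted p = 0.846). MARVELD3 and the cadherin CDH1 rose by 0.88 and 0.56, and CLDN16 and CLDN8 fell by 1.38 and 1.05. Of 14 mesenchymal transition genes, 6 rose and 4 fell (camera adjusted p = 0.523); MMP2 went from 8 to 94 counts and FN1 from 12 to 81 over the group, MMP10 fell from 15 ± 1.88 to 2.96 ± 1.5 CPM and SPARC fell by 1.05.

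The rule for the largest changes also named genes outside these lists. CLEC7A (dectin-1, a receptor for fungal glucans) rose from 1.43 ± 0.473 to 38.7 ± 4.11 CPM, log2 fold change 4.74 (SE 0.16, edgeR adjusted p = 2.74e-13). The transmembrane glycoprotein GPNMB rose from 42.5 ± 13.5 to 659 ± 32.3 CPM, the matrix protease MMP7 from 1.42 ± 0.522 to 19.1 ± 0.516 CPM, and connexin 43 (GJA1) from 4.4 ± 0.123 to 45.5 ± 4.06 CPM. The efflux pump gene ABCG2 had the largest fall, from 14.1 ± 2 to 0.862 ± 0.277 CPM, log2 fold change -4.04 (SE 0.21, edgeR adjusted p = 3.23e-11). TNNT3, a fast muscle troponin, fell by 3.29, the arginine transporter SLC7A2 fell by 2.86 and ELFN2 fell by 2.74 on the log2 scale. The imprinted noncoding RNA H19 fell from 1790 ± 76.2 to 309 ± 77.5 CPM, log2 fold change -2.54 (SE 0.20, edgeR adjusted p = 0.000288). The pseudogene KRT42P and LOC400891 fell by 2.81 and 2.61.

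Camera called none of the lists for cell types other than airway epithelium or for dissociation stress. Fibroblast genes had 0 of 3 higher and COL1A1 lower in edgeR (1 higher at an unadjusted p under 0.05; DESeq2 called 0 of 6 higher and 3 lower), with 1 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.846). COL1A1 fell from 15.7 ± 1.5 to 10.3 ± 0.884 CPM. Of 4 fibroblast genes tested, 1 was higher without normal replicate 1 or squamous replicate 1, and 2 were lower without normal replicate 1 or squamous replicate 3. Of 5 leukocyte genes, 3 rose and LAPTM5 fell (camera adjusted p = 0.523), with CD68 higher, at 26.7 ± 1.48 and 48 ± 4.46 CPM, and CORO1A higher by 0.90. Of 5 endothelial genes, 2 rose and 2 fell, with a median of 0.09, a mean of -0.26 and a camera direction of up (adjusted p = 0.846), all at low counts: CDH5 went from 9 to 52 counts over the group, KDR from 83 to 184, CLDN5 from 64 to 8 and TEK from 43 to 7. Of 3 alveolar genes, ABCA3 fell in edgeR and 0 rose (1 higher at an unadjusted p under 0.05, 0 in DESeq2), or 1 higher and 1 lower when adjusted over the list alone, with a median of 0.17, a mean of -0.20 and a camera direction of up (adjusted p = 0.846). The ABCA3 call (edgeR adjusted p = 0.0264) was lost without normal replicate 1 or 2 or squamous replicate 2 or 3 (edgeR adjusted p of 0.0611 to 0.118), and 1 alveolar gene was higher without normal replicate 3 or squamous replicate 3. Of 18 dissociation stress genes, 11 rose and 5 fell (camera adjusted p = 0.0795; fry adjusted p = 0.0207), with FOS and IER3 higher by 1.98 and 1.79 and the heat shock genes HSPA1A and HSPH1 each lower by 0.94. Among the 29 lists, camera with the preset correlation called 12, of which 10 were up and 2 down. With an estimated correlation it called 0, with 0 also at an unadjusted p under 0.05, while fry, which asks whether a list's own genes move one way, called 19. Besides dissociation stress, fry called these lists that camera did not: xenobiotic metabolism (fry adjusted p = 0.000454), Wnt targets (0.00248) and pattern recognition receptors (0.00298). The others were mesenchymal transition (fry adjusted p = 0.0202), ionocyte (0.0283) and neuroendocrine cell (0.0332). In each list given with a single pair of counts, those adjusted over the list alone were equal to them.

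**Figure D3:**
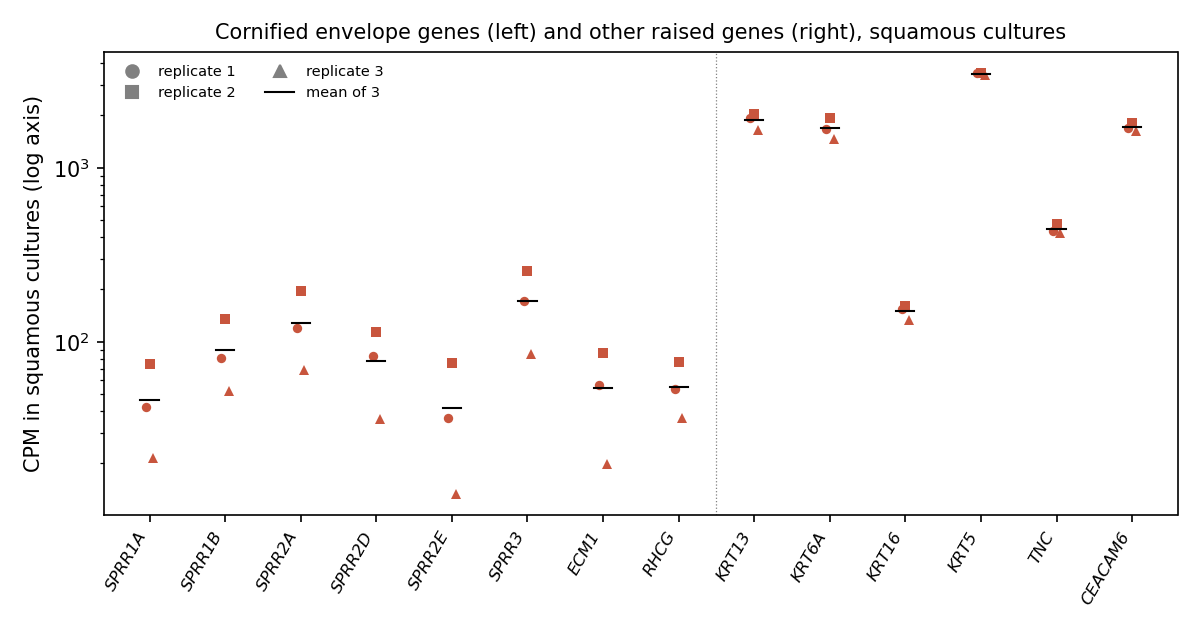
CPM on a log axis of 8 cornified envelope genes and 6 raised genes of other lists in the 3 squamous libraries, with symbols for replicates and a bar for the mean of 3. The genes drawn are chosen examples, and ECM1 was not past the threshold (edgeR adjusted p = 0.0945). Some envelope genes not drawn varied little, such as CSTA at 283, 291 and 243 CPM in replicates 1, 2 and 3. KRT78, a raised keratin not drawn, varied widely, at 42.1, 60.1 and 20.8 CPM. SPRR2A was at 120, 196 and 68.5 CPM in replicates 1, 2 and 3, while KRT13 was at 1940, 2030 and 1650 CPM, and all 11 squamous keratins were higher in replicate 2 than in replicate 3.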

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

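The alternatives below were chosen before the data were examined. The number of genes changed stayed within 1.5 times of 7464 under each except the minimum fold of 2, which called 649 genes (186 higher, 463 lower) because it tests a larger change. It was 7470 with RLE and 7532 with upper-quartile scaling, 7112 in DESeq2, 7399 in limma-voom, 7645 with no filter and 7281 with 1 CPM in 3 libraries. Leaving out 1 library gave 6603 to 7317 genes (3220 to 3662 higher, 3363 to 3655 lower), with fewer samples in the fit. Of the genes called in both fits, 0 changed sign under any alternative. The share of higher genes was 48% with TMM and 51.1% with upper-quartile scaling, and neither scaling moved the median of all genes by more than 0.019.

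The replicate numbers were not taken as pairing. Deviations of same-numbered libraries correlated at 0.17, -0.11 and 0.14 across 10526 genes, and normal replicate 1 correlated more with squamous replicate 2 (0.21). With the number as a block, 7687 genes were called (3704 higher, 3983 lower) and 12 lists. The block ended the calls of SPRR2E (edgeR adjusted p = 0.0584) and KRT17 (0.136), and the cornified envelope list then had 9 members higher, against 17 without it. The cause was not tested.

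The number of lists called was 12 with RLE or upper-quartile scaling, 13 with no filter, 11 with 1 CPM in 3 libraries and 10 to 13 without 1 library. With an estimated correlation it was 0, where the correlation estimated for each of the 12 lists exceeded the preset 0.01. The size of the correlation does not account for all of this. The pattern recognition receptor list was estimated at -0.0087, below the preset, yet its unadjusted camera p went from 0.0547 to 0.11. The fits therefore differ in more than the correlation. Among the lists, 315 of 347 values kept their direction and side of the threshold, 18 lost the call, 3 gained it and 11 turned direction. Lists not called in either fit turned as follows, given as the median log2 fold change. Ion and fluid transport was at -0.1 with RLE, -0.09 with upper-quartile scaling and -0.08 with the block, and ran from -0.16 to 0.09 without 1 library. Notch pathway was at 0.06 with no filter. The alveolar list was at -0.75 with no filter and ran from 0.05 to 0.3 without 1 library, where it turned at 0.2 without squamous replicate 1. Endothelium ran from -0.11 to 0.24 and turned at 0.24 without squamous replicate 3. Direction is that of camera, which can differ in sign from the median. TP63, not called in any fit, ran from -0.04 to 0.08 without 1 library and was not above 0 without normal replicate 3, squamous replicate 2 or squamous replicate 3. The cause was not tested. Among 118 named genes, 1543 of 1645 values kept direction and side of the threshold, 97 lost the call, mostly under the minimum fold of 2, and 2 gained it: SCGB1A1 and PLCG2, both without normal replicate 3. In the simulation, where a far smaller share of genes changed than in the data, changes of 1.5-fold were recovered for 74% of genes. A gene not called can still differ by a small fold.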

Other observations

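The tests in this part were chosen after the result was seen, except the counts over other splits of the libraries. Some of the genes raised at least 2-fold lay in runs of neighbours in the genome, 41 of 503. Among 14487 tested genes placed on a single chromosome, windows of 10 neighbours held up to 9 raised genes, where 1000 shuffles of the 503 raised genes gave at most 6. Windows above the 95th percentile of the shuffles (5 genes) formed 5 runs, and 0 runs were found for the 1157 genes lowered at least 2-fold, where the highest window held 6 and the shuffles' percentile was 6. The 9 raised genes argue against chance placement, though family members in a run can share reads. Most genes of that window were SPRR genes, with edgeR adjusted p of 0.0122 to 0.0414, and the SPRR2E and SPRR2F calls were lost in several fits. The highest windows of the other runs held 6 or 7 raised genes. With coordinates as the table gives them, the runs were the epidermal differentiation complex on chromosome 1 (152285935 to 153363664; 13 of 16 genes raised), keratins on chromosome 12 (52817854 to 53242778; 6 of 7) and chromosome 17 (39133968 to 39780882; 7 of 9), the chemokine and growth factor cluster on chromosome 4 (74606223 to 75975325; 9 of 13) and the kallikreins on chromosome 19 (51446559 to 51845378; 6 of 10).

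The kallikrein run went both ways. The genes for KLK5 and KLK7, proteases that shed cells of the cornified layer, rose by 2.49 and 2.84 on the log2 scale, and KLK6 and KLK8 by 2.54 and 2.50. Their neighbours KLK10, KLK11 and KLK13 fell by 1.28, 1.92 and 2.23 (edgeR adjusted p = 0.00308, 2.99e-11 and 3.48e-05). On chromosome 12, KRT4 fell between the raised KRT5 and KRT78. On chromosome 4, the epidermal growth factor receptor ligand genes EPGN and AREG rose by 4.03 and 1.13, while BTC fell by 0.45 (edgeR adjusted p = 0.0289). EPGN was near the floor in normal cultures, at 0 to 0.339 CPM.

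In the real grouping, 7464 genes and 12 lists were called. Among the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one, and the highest of the others gave 0. For lists, 2 splits gave as many, and the highest of the others gave 13. With 10 splits, a share under 0.05 cannot be reached. Each other split also puts libraries of both groups on each side. The real difference then adds to the spread within sides, so these counts are not those of data without a difference.

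Multiciliated cell genes fell by unequal amounts, with log2 fold changes from -2.01 for GMNC to -0.01 for CCNO among the 41 members. An equal fall of every member is argued against by differences among members that recurred in separate libraries. Across members, changes in pairings of a normal with a squamous library that share no library correlated at 0.77 to 0.94 in 18 comparisons; genes are not independent replicates. Gene length and level are argued against for the fall of the list by 10000 random lists matched on both, whose lowest median was -0.23 against -1.21, and as the main source of the differences by a linear fit on both that took 8.71% of their variance. A loss of multiciliated cells stays open, since other cells can hold part of a member's transcripts, as do transcript stability and the treatment.

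Cornified envelope genes differed among the squamous cultures, with 25 of 29 members higher in squamous replicate 2 than in replicate 3 and a median log2 ratio of 1.01. For squamous replicate 1 against replicate 3 the median was smaller, at 0.34, so a high replicate 2 can hold much of the spread. The difference between replicates 2 and 3 was not particular to this list. Its median ratio was 0.64 for antimicrobial, 0.56 for inflammatory cytokine and 0.41 for squamous keratin genes, and -0.22 for multiciliated cell genes. A share of normal culture in squamous replicate 3 as the source of that whole difference is argued against by 10000 lists matched on fold change and level, the highest of which reached 0.37. A smaller share stays open: the 496 other genes raised at least 2-fold had a median ratio of 0.12, the 1166 lowered had -0.16, and each normal library correlated most with squamous replicate 3 across genes (0.9662 for normal replicate 1, against 0.9597 with squamous replicate 2). The envelope genes also varied among normal cultures, where the list's median log2 ratio of replicate 1 to replicate 2 was 0.36. What made the cultures differ stays open, and no biological explanation was tested.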
